A study of Rattus norvegicus with 10 samples.

How the data were processed

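RNA of rat mammary gland was measured on 10 oligonucleotide arrays of the Affymetrix RAE230 design. Each array carried RNA pooled from 2 animals of 1 diet, per the labels' protocols. The groups were taken from the sample titles: 3 arrays of the CAS diet, 4 of the SPI diet and 3 of the GEN diet. The labels call the source epithelial cells, the labelling protocol speaks of mammary gland, and the design text also mentions colon. The samples are described here as mammary gland.

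The authors deposited 1 table of signal intensity per probe set, on a linear scale, made with MAS5 per the submitters' processing notes. The version of that software is not given in the sources used here. The intensity values of the deposited table looked globally scaled, since the mean of each array after leaving out 2% of the probe sets at each end lay at about 500 on every array (499.81 to 499.83). MAS5 scales each array as a whole, so differences between arrays in total RNA are not visible in these values. The table holds no calls of presence or absence, so a dim probe set was recognised only by its signal. No column belonged to a sample outside the series.

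The table held 15923 probe sets. The 57 control probe sets were left out, which left 15866. Values under 1, which were 0.0637% of all values, were set to 1 before log2 was taken. Probe sets in the lowest 40% of mean log2 signal over the 10 arrays were left out, and 9520 probe sets were tested. The lowest of these had a geometric mean signal of 162. Gene symbols came from the platform annotation, updated through Entrez gene identifiers. Of the 15866 probe sets, 12783 had 1 gene symbol, 312 had several and 2771 had none in the annotation used here. The identifiers of 12748 probe sets were found in the current gene table and 0 symbols changed. The named probe sets covered 10411 genes, and no gene was named from a probe set with several symbols.

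Differences between diets were tested on log2 signal with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend). All 10 arrays entered 1 fit so that the 3 diets shared an estimate of the spread, with 7 residual degrees of freedom, or 12.9 with the prior. The Benjamini-Hochberg adjustment ran over the 9520 probe sets of each comparison, and an adjusted p under 0.05 counted as a difference. Errors of log2 differences are standard errors of the fit. Signals of groups are means and standard deviations over arrays. The number of arrays limits the precision: the median 95% interval of a log2 difference reached 0.41 to either side for SPI against CAS, 0.44 for GEN against CAS and 0.41 for SPI against GEN.

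Gene groups were 29 lists of cell type markers and pathways. They were tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each of 7119 genes. A list needed 5 tested genes, which 26 lists had, and the adjustment ran over the 78 tests of 26 lists in 3 comparisons. Camera asks whether the genes of a list shifted more than other genes. Each test was repeated with the correlation estimated from the residuals and with fry, which asks whether the genes of a list moved 1 way on balance without setting them against other genes. Members were also adjusted over the list alone. The mean of a list per array was compared between diets with an equal-variance model over the 10 arrays, which gives the error printed beside a list mean.

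The diets, comparisons, filter, test, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule took, for each comparison, the 12 highest and the 12 lowest log2 differences among single-symbol probe sets past an adjusted p of 0.05 whose groups did not overlap. With fewer than 10 such genes, it took those at an unadjusted p under 0.01 without overlap, given as values that did not pass. A gene with several probe sets was named by the brightest. The rule added the passing members of each list, or otherwise 2 to 4 members with the smallest p, and the receptors Esr1, Esr2 and Pgr. Single genes outside the rule are said to have been chosen after their values were seen.

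The model was tested on simulated data with independent normal noise of the fitted variance of each probe set, and with 200 of 9520 probe sets changed. For SPI against CAS, 82% of changes of 1 log2 unit and 98% of changes of 2 log2 units were recovered, and 10 of 190 calls were false. For GEN against CAS the shares were 76% and 97% with 6 false calls of 179, and for SPI against GEN 81% and 100% with 8 of 189. On the same simulated data, camera gave 2 of 100 unchanged random lists an unadjusted p under 0.05, and a list raised by 0.5 log2 units a p of 8.53e-24. Genes were independent in these simulations, so they do not test camera where the genes of a list are correlated. They also held no variation common to a whole array, and 200 planted changes make the adjusted threshold easier to reach. The recovered shares therefore do not show that such changes were absent where the real data gave no calls.

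The responses to SPI and GEN share the CAS arrays, so their correlation was set beside 100 simulations of unchanged groups of the same sizes with 1 shared reference group. Each simulated array was a random mixture of the residuals of the real arrays, and the overlap of probe sets at an unadjusted p under 0.01 was counted in the same draws. This form of simulation replaced a first one, which permuted the residuals, after the result of the first had been seen. Splits of the arrays into groups of the same sizes were refitted, 35 for 3 against 4 arrays and 10 for 3 against 3. RNA quality was read from the 3'/5' signal ratios of the beta-actin and GAPDH control probe sets, which the labels name as quality controls.

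The alternatives were quantile normalization, centring of each array on its median, no filter, a filter on the lowest 60%, an offset of 32 before log2, eBayes without trend, a fit of only the 2 groups compared, the replicate number as a block, a plain equal-variance test per probe set, 1 probe set per gene, and leaving out each array in turn. After the arrays had been seen, the log2 beta-actin ratio as a covariate and the fit of GEN against CAS without SPI replicate 4 were added. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3 in Python 3.11.15. Scanner images and probe-level data were not used here.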

Results

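Gene expression was profiled in the mammary gland of female Sprague-Dawley rats at postnatal day 50, after feeding on 1 of 3 purified diets named CAS, SPI and GEN. The question, by the title of the series, was how SPI or genistein in the diet alters the expression profile of mammary epithelium. GEN is genistein, a soy isoflavone that binds estrogen receptors. The labels do not spell out the other names; from knowledge of the study rather than from the labels, CAS stands for casein and SPI for soy protein isolate, and CAS is taken as the reference diet. There were 3 CAS arrays (replicates 1, 2 and 3), 4 SPI arrays (replicates 2, 3, 4 and 5) and 3 GEN arrays (replicates 1, 3 and 5). Each array carried RNA of 2 pooled animals. The labels describe 3 replicate labelled targets per RNA pool and do not say which arrays share a pool. The mean log2 signal of the macrophage list ran from 8.96 to 10.16 over the CAS arrays. It ran from 8.70 to 9.61 on SPI and from 8.82 to 9.79 on GEN. Such spread argues against all arrays of a diet sharing 1 pool. Some arrays may still share one, so the p-values may in part measure technical spread.

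Lalba, the alpha-lactalbumin that takes part in lactose synthesis, had a mean signal of 11993 ± 3743 (SD, n = 3) on CAS. The arrays had median signals of 222.8 to 256.7. Pairs of arrays of the same diet correlated across probe sets with a median r of 0.952 (12 pairs), and pairs of different diets with 0.951 (33 pairs); probe sets are not independent replicates.

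The beta-actin 3'/5' signal ratio, a measure of RNA integrity in which high values mean shorter transcripts, was 4.60 ± 0.496 (SD, n = 3) on CAS, 5.15 ± 2.00 (SD, n = 4) on SPI and 3.91 ± 1.17 (SD, n = 3) on GEN. SPI 4 stood at 7.77 and GEN 5 at 2.83. The GAPDH ratio of SPI 4 was 2.91, against 1.18 to 1.89 on the other 9 arrays. Over all 10 arrays the actin ratio went with the first principal component, which held 25.1% of the variance, at a Pearson r of 0.805 (permutation p = 0.00693, adjusted 0.0139 over 2 components, n = 10). The Spearman correlation was 0.697 (permutation p = 0.0305, adjusted 0.0610, n = 10). Without SPI 4 and GEN 5, the arrays farthest from the median ratio, r was 0.406, so the relation rested on those arrays. With the second component (17.9% of the variance) r was 0.0239 (permutation p = 0.930, adjusted 0.930, n = 10), the Spearman correlation was 0.103 (permutation p = 0.786, adjusted 0.786) and r without the same arrays was 0.309.

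**Figure D1:**
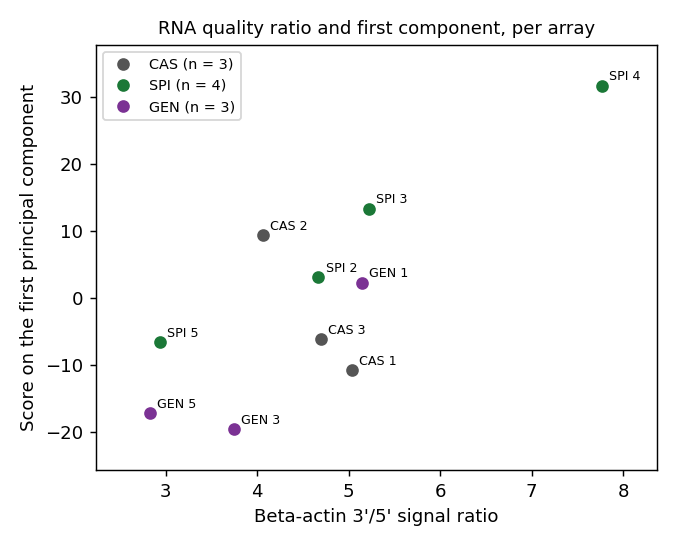
Beta-actin 3'/5' signal ratio (x axis, no unit) against the score on the first principal component of log2 signal (y axis, no unit), 1 point per array, coloured by diet. SPI 4 lies apart at a ratio of 7.77 and a score of 31.7, and without SPI 4 and GEN 5 the correlation over the arrays is 0.406.

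On the SPI diet, compared with CAS, the class I antigen gene RT1-CE16 and Reg3b had the lowest log2 differences among the genes that met the naming rule, whose groups did not overlap. Lists of macrophage, lymphocyte and mast cell genes were called lower by camera, but not with an estimated correlation (adjusted p = 0.595 for each). Reg3b, a secreted antimicrobial lectin, had a signal of 118 ± 40.7 (SD, n = 4) on SPI against 401 ± 89.0 (SD, n = 3) on CAS, a log2 difference of -1.81 ± 0.27 (SE). RT1-CE16, which codes for a class I histocompatibility antigen, had a log2 signal of 6.09 ± 1.11 (SD, n = 4) against 8.69 ± 0.35 (SD, n = 3), a difference of -2.61 ± 0.47 (SE). Its probe set is of the kind that can also bind transcripts of related genes. On SPI, Reg3b and RT1-CE16 had signals below 162, the lowest mean signal tested, so the sizes of these differences are uncertain. P3h3, a collagen prolyl hydroxylase, differed by -1.05 ± 0.19 and Il17b, a cytokine, by -1.02 ± 0.23. At the upper end of the genes that met the rule, Rrad, a small GTPase of muscle, had 507 ± 104 (SD, n = 4) against 253 ± 60.7 (SD, n = 3), a difference of 1.01 ± 0.21 (SE), and Apod, a lipid-carrying apolipoprotein, differed by 0.72 ± 0.17. None of these genes passed: the adjusted p in limma was 0.170 for Reg3b, 0.292 for RT1-CE16 and for P3h3, 0.568 for Rrad, and 0.582 for Il17b and for Apod.

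The remaining named genes of this comparison also did not pass. Lower on SPI were Cdh22 (-1.58), Fndc1 (-1.49), Rprm (-1.33), Mapkapk3 (-1.28), Dact2 (-1.21), Rac2 (-1.03), the leukocyte phosphatase Ptprc (-1.01) and the ribosomal protein gene Rpl37a (-0.96). Higher were Ppp1r14a (0.81), the transferrin receptor Tfrc (0.75), the myelin gene Mbp (0.71), Rab3d (0.71), Bcr (0.70), the vitamin transporter Slc5a6 (0.69), Dmpk (0.68), Rfc3 (0.64), Mamdc2 (0.63) and Jph2 (0.62). Other probe sets of some of these genes differed: the other one of Tfrc stood at 0.12, a dim one of Mbp at -0.35, a dim one of Cdh22 at -0.70, and a dim one of Ptprc at -2.59. Without CAS 1, Fndc1 stood at -0.89 and Dact2 at -0.71, and without CAS 3, Mbp stood at 0.43 and Bcr at 0.38.

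**Figure D2:**
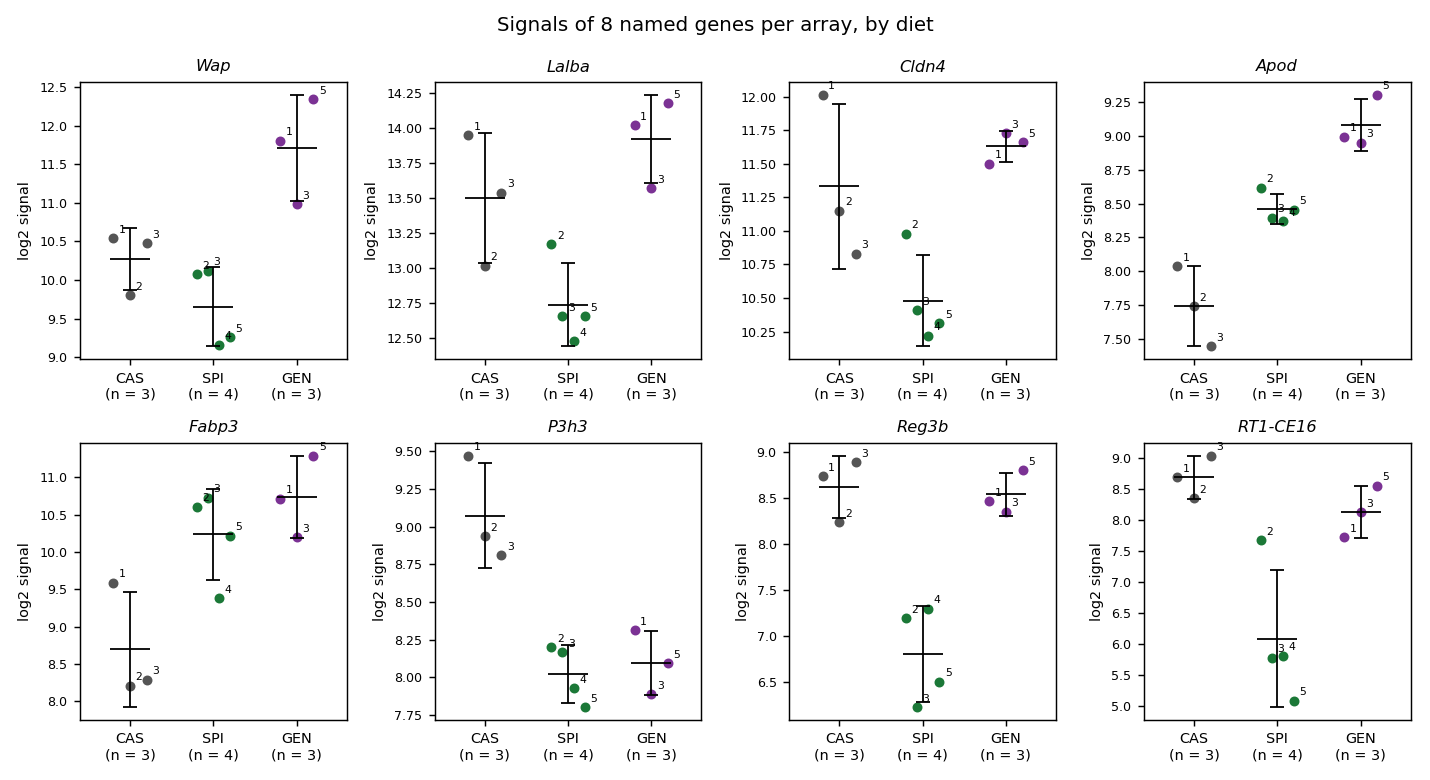
Log2 signal (y axis) of Wap, Lalba, Cldn4, Apod, Fabp3, P3h3, Reg3b and RT1-CE16 on each array (points, with replicate numbers), by diet (x axis, 3 CAS, 4 SPI and 3 GEN arrays), with the mean and SD of each diet as bars. Wap and Lalba have their highest mean on GEN, Apod and P3h3 separate CAS from both other diets, and SPI 2 lies above the other SPI arrays for RT1-CE16.

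Of the 26 lists, 10 were called by camera for SPI against CAS, 4 higher and 6 lower. Macrophage and myeloid genes were lower in 18 of 19 members, with a list mean of -0.66 ± 0.39 (SE) and an adjusted p of 4.78e-08 (adjusted p = 0.595 with an estimated correlation). The members with the smallest p were the lysosomal glycoprotein gene Cd68 (-0.74), the chemokine Ccl6 (-1.52) and the complement genes C1qa and C1qc (-1.14 each), and 0 members passed when adjusted over the list alone or over all genes. Lymphocyte genes were lower in 8 of 9 members, with a mean of -0.57 ± 0.24 and an adjusted p of 9.45e-05 (adjusted p = 0.595 with an estimated correlation); Rac2 and Ptprc, which are expressed in leukocytes of many kinds, passed adjusted over the list alone and 0 over all genes. The T cell genes Lck and Cd247, chosen after the result was seen, had mean signals of 474 and 167 on SPI (n = 4) against 430 and 171 on CAS (n = 3). Mast cell genes were lower in 9 of 10 members (mean -0.59 ± 0.39, adjusted p = 0.000768, and 0.595 as the adjusted p with an estimated correlation), and Hdc, the histidine decarboxylase that makes histamine, passed adjusted over the list alone at -0.92 ± 0.21. Interferon response genes were lower in 18 of 26 members (mean -0.16 ± 0.07, adjusted p = 0.0233, and 0.595 as the adjusted p with an estimated correlation), led by Irf7 at -0.67, and 0 passed adjusted over the list alone. Without CAS 2 the macrophage mean was -1.01. Without CAS 1 the mast cell call was lost at -0.35. The interferon call was lost without CAS 1 (-0.14), CAS 3 (-0.12) or SPI 2 (-0.13).

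Fibroblast genes were lower on SPI in 16 of 22 members, with a mean of -0.37 ± 0.21 (SE) and an adjusted p of 0.00117 (adjusted p = 0.595 with an estimated correlation). Adjusted over the list alone, Pi16 (-1.20) and Clec3b (-1.17) were lower and the intermediate filament gene Vim was higher (0.42), and 0 passed over all genes. Luminal epithelial genes were lower in 15 of 17 members (mean -0.23 ± 0.24, adjusted p = 0.0147, and 0.667 as the adjusted p with an estimated correlation), led by the tight junction gene Cldn4 at -0.85, and 0 passed adjusted over the list alone. Proliferation genes were higher in 27 of 29 members (mean 0.21 ± 0.15, adjusted p = 1.88e-06, and 0.595 as the adjusted p with an estimated correlation), with the DNA replication gene Mcm4 at 0.50 and Stmn1 at 0.49. Endothelial and pericyte genes were higher in 17 of 17 members (mean 0.20 ± 0.14, adjusted p = 9.33e-05, and 0.595 as the adjusted p with an estimated correlation), with the endothelial claudin Cldn5 at 0.53; 0 members of either list passed adjusted over the list alone. Schwann cell genes were higher in 7 of 8 members (mean 0.30 ± 0.08, adjusted p = 0.00379, and 0.595 as the adjusted p with an estimated correlation), and the nerve sodium channel Scn7a (0.85) and Mbp (0.71) passed adjusted over the list alone. Amino acid and ER stress genes were higher in 19 of 31 members (mean 0.12 ± 0.10, adjusted p = 0.0278, and 0.595 as the adjusted p with an estimated correlation), with Phgdh, which opens serine synthesis, at 0.89, and 0 passed adjusted over the list alone. The highest actin ratio, that of SPI 4, went with the lowest luminal mean, and without SPI 4 the luminal call was lost at -0.06. Without CAS 1, which had high signals of muscle genes, the calls of the luminal (-0.07), fibroblast (-0.19) and endothelial (0.08) lists were lost, and without CAS 2 the luminal mean was -0.36 and the endothelial mean 0.34. Cldn4 stood at -0.51 without CAS 1 and Phgdh at 0.26 without CAS 3. The amino acid call was lost without CAS 2 (0.10), CAS 3 (0.04), SPI 4 (0.09) or SPI 5 (0.11), and its mean without CAS 1 was 0.23. The Schwann cell call was lost at 0.04 with no filter on dim probe sets, and the amino acid call at 0.12 with quantile normalization.

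**Figure D3:**
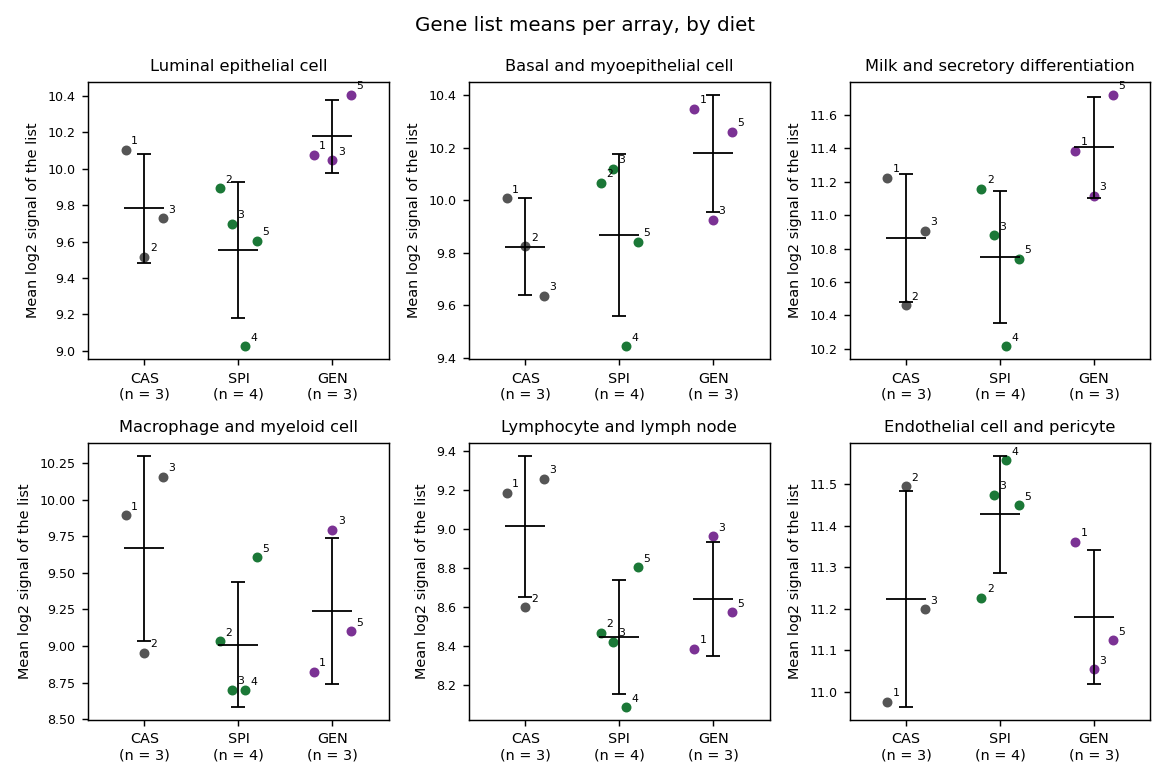
Mean log2 signal (y axis) of the tested genes of 6 lists on each array (points, with replicate numbers), by diet (x axis, 3 CAS, 4 SPI and 3 GEN arrays), with the mean and SD of each diet as bars. The luminal mean is 9.55 on SPI and 10.18 on GEN, and the macrophage mean is 9.01 on SPI and 9.67 on CAS, with CAS 2 near the SPI arrays.

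Over all 9520 probe sets, limma called 0 between SPI and CAS at an adjusted p under 0.05, and the smallest adjusted p was 0.170. At an unadjusted p under 0.05 there were 459, of which 146 were higher on SPI and 313 lower, where 476 are expected by chance. eBayes without trend and the plain test per probe set also gave 0 adjusted calls, with 449 and 357 probe sets at an unadjusted p under 0.05. With each array centred on its median the split turned to 300 higher and 174 lower, a share of 63.3% higher against 31.8%, so the balance of directions over all probe sets was not determined. The groups did not overlap for 438 probe sets (4.60%), where chance gives 5.71%. The unadjusted count was 726 without CAS 2 and 298 without SPI 3. Without SPI 2, 2 probe sets passed: RT1-CE16 at -3.14 with an adjusted p of 0.00227 in limma (0.00227 to 0.9999 over the alternatives) and the class II gene RT1-Bb, noted after its values were seen, at -3.96. A split that set SPI 2 with the CAS arrays also gave 2 adjusted calls. Differing MHC haplotypes, raised below for RT1-Bb, were not tested for RT1-CE16.

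On the GEN diet, compared with CAS, lists of milk genes, luminal and basal epithelial genes and genes of fatty acid synthesis were called higher by camera, and extracellular matrix genes lower. None of these 5 was called with an estimated correlation (adjusted p = 0.595 for each). The luminal and basal means rose by similar amounts (0.39 and 0.35). Whether the GEN pools held a larger share of epithelium was not tested. Apod had a signal of 546 ± 75.3 (SD, n = 3) on GEN against 217 ± 44.4 (SD, n = 3) on CAS, a log2 difference of 1.34 ± 0.18 (SE), with the smallest adjusted p of the comparison, 0.0642 in limma. Wap, the whey acidic protein of rodent milk, had 3608 ± 1593 (SD, n = 3) against 1269 ± 326 (SD, n = 3), a difference of 1.44 ± 0.35 (SE). Fabp3, a fatty acid binding protein, had 1785 ± 671 (SD, n = 3) against 459 ± 269 (SD, n = 3), a difference of 2.04 ± 0.41 (SE). Acvr2a, an activin receptor, was at the lower end with -1.10 ± 0.18, and P3h3 differed by -0.98 ± 0.21. None passed: the adjusted p in limma was 0.766 for Wap, 0.462 for Fabp3, 0.135 for Acvr2a and 0.577 for P3h3.

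Among the other named genes of this comparison, which also did not pass, those higher on GEN were Fabp9 (2.35), Clca1 (2.02), Phgdh (1.51), the carbonic anhydrase Car2 (1.40), Lgals7 (1.30), the respiratory chain gene Ndufb8 (1.21), the fatty acid desaturase Fads2 (1.20), Scn7a (1.13) and Tfrc (1.10). Those lower were the leukocyte sialoprotein Spn (-1.48), Pi16 (-1.41), the collagen gene Col5a3 (-1.34), Cd248 (-1.32), Cdh22 (-1.28), Uqcc3 (-1.23), Hs1bp3 (-1.21), the complement regulator Cd55 (-0.96), Stab1 (-0.92) and Adgre5 (-0.83). The other probe sets of Tfrc and Car2 stood at 0.88 and 0.80, and those of Cd55, Cd248 and Cdh22, which lay below the filter, at -0.16, -0.51 and -0.47. Without CAS 3, Fabp9 stood at 1.11, Phgdh at 0.88, Ndufb8 at 0.69 and Spn at -0.97. Cd248 stood at -0.85 without CAS 1, and Col5a3 at -0.89 and Hs1bp3 at -0.75 without GEN 3.

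Camera called 11 lists for GEN against CAS, 8 higher and 3 lower. Milk and secretory genes were higher in 16 of 18 members, with a list mean of 0.54 ± 0.30 (SE) and an adjusted p of 3.75e-07 (adjusted p = 0.595 with an estimated correlation). Wap and the lipid droplet gene Plin2 (0.70) passed adjusted over the list alone and 0 over all genes, and the casein Csn1s1 stood at 0.78. The other probe set of Plin2 stood at -0.10. Luminal epithelial genes were higher in 16 of 17 members (mean 0.39 ± 0.25, adjusted p = 5.51e-07, and 0.595 as the adjusted p with an estimated correlation), led by the tetraspanin Cd9 at 0.73. Basal and myoepithelial genes were higher in 14 of 15 members (mean 0.35 ± 0.21, adjusted p = 0.000556, and 0.595 as the adjusted p with an estimated correlation), with Lgals7 at 1.30 and the basal keratin Krt5 at 0.91. Proliferation genes were higher in 24 of 29 members (mean 0.21 ± 0.16, adjusted p = 1.60e-05, and 0.595 as the adjusted p with an estimated correlation), with the cyclin Ccnb2 at 0.63; 0 members of these 3 lists passed adjusted over the list alone. Fatty acid and triglyceride synthesis genes were higher in 13 of 18 members (mean 0.25 ± 0.11, adjusted p = 0.00117, and 0.595 as the adjusted p with an estimated correlation), where Fads2 passed adjusted over the list alone and Thrsp stood at 0.80. The list of fatty acid oxidation was not called (adjusted p over 0.05), but its member Fabp3 passed adjusted over the list alone here and for SPI against CAS (1.54). GEN 5, with the lowest actin ratio of all arrays (2.83), had the highest milk mean (11.72) and luminal mean (10.41). With the ratio as a covariate, chosen after the arrays were seen, the milk difference was 0.47 and the luminal difference 0.31, and both stayed called. The means were smaller without CAS 2 for the milk list (0.34) and the luminal list (0.26), and Csn1s1 then stood at 0.46. The mean of the proliferation list was 0.36 without GEN 3 and 0.10 without GEN 5, and the basal call was lost without CAS 3 at 0.26.

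Extracellular matrix genes were lower on GEN in 34 of 41 members, with a mean of -0.20 ± 0.15 (SE) and an adjusted p of 0.00117 (adjusted p = 0.595 with an estimated correlation). Col5a3 (-1.34) and Col6a3 (-0.51), both collagen chains, led it. Macrophage genes were lower in 14 of 19 members (mean -0.43 ± 0.42, adjusted p = 0.0132, and 0.667 as the adjusted p with an estimated correlation), with C1qa at -1.06. Lymphocyte genes were lower in 7 of 9 members (mean -0.37 ± 0.26, adjusted p = 0.0278, and 0.612 as the adjusted p with an estimated correlation), with Ptprc at -0.77. Antioxidant genes were higher in 19 of 26 members (mean 0.17 ± 0.15, adjusted p = 0.00195, and 0.595 as the adjusted p with an estimated correlation), with the glutathione transferase Gsta1 at 0.45. Amino acid and ER stress genes were higher in 20 of 31 members (mean 0.15 ± 0.11, adjusted p = 0.0216, and 0.595 as the adjusted p with an estimated correlation), with Phgdh at 1.51 and Psat1, also of serine synthesis, at 0.68. Adipocyte genes were higher in 12 of 18 members (mean 0.11 ± 0.05, adjusted p = 0.0295, and 0.595 as the adjusted p with an estimated correlation), with Sncg at 0.87 and the adipokine Cfd at -1.01. In each of these 6 lists 0 members passed adjusted over the list alone or over all genes. Pi16 of the fibroblast list (-1.41), and Mbp (1.10) and Scn7a (1.13) of the Schwann cell list, passed adjusted over the list alone, although camera called neither list. Fry in either direction called the Schwann cell list (adjusted p = 0.00239). The matrix call was lost without CAS 1 (-0.04). The macrophage call was lost without CAS 1 (-0.32), CAS 3 (-0.21), GEN 1 (-0.22) or GEN 5 (-0.36), and the mean was -0.79 without CAS 2 and -0.71 without GEN 3. The lymphocyte call was lost without CAS 1 (-0.29), CAS 3 (-0.25), GEN 1 (-0.25) or GEN 5 (-0.34), and the mean was -0.58 without CAS 2. The antioxidant call was lost without CAS 3 (0.05) or GEN 3 (0.07), and its mean was 0.31 without CAS 1. The amino acid call was lost without CAS 2 (0.13), CAS 3 (0.07) or GEN 3 (0.12), with 0.26 without CAS 1. Cfd stood at -0.60 without GEN 1. The adipocyte call was lost without CAS 3 (0.12), GEN 3 (0.14) or GEN 5 (0.07), with 0.07 without CAS 2. With no filter the adipocyte (0.03) and lymphocyte (-0.13) calls were lost, and with quantile normalization the adipocyte call (0.10).

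limma called 0 of 9520 probe sets between GEN and CAS, and 2 had an adjusted p under 0.1, Apod and a probe set with no gene symbol. At an unadjusted p under 0.05 there were 561, of which 257 were higher on GEN and 304 lower, against 476 expected by chance. eBayes without trend and the plain test gave 0 adjusted calls, with 537 and 505 at an unadjusted p under 0.05. The groups did not overlap for 1058 probe sets (11.1%), where chance gives 10%. Apod passed without CAS 1 (1.49, adjusted p = 0.0463), with the lowest 60% of probe sets left out (adjusted p = 0.0463) and with 1 probe set per gene (adjusted p = 0.0408), all in limma, with adjusted p from 0.0408 to 0.885 over the alternatives. Without GEN 5 the unadjusted count was 353.

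Between SPI and GEN, the lists of milk genes and of luminal epithelial genes were called lower on SPI by camera, but not with an estimated correlation (adjusted p = 0.595 for each) or by fry (adjusted p = 0.583 for each). Wap had a signal of 844 ± 291 (SD, n = 4) on SPI against 3608 ± 1593 (SD, n = 3) on GEN, a log2 difference of -2.06 ± 0.33 (SE). Lalba had 6963 ± 1545 (SD, n = 4) against 15757 ± 3245 (SD, n = 3), a difference of -1.18 ± 0.22 (SE). Csap1, named for a salivary protein, had 230 ± 106 (SD, n = 4) against 1272 ± 442 (SD, n = 3), a difference of -2.56 ± 0.54 (SE). Cldn4 differed by -1.15 ± 0.25 and the epithelial cadherin Cdh1 by -1.13 ± 0.31. None passed: the adjusted p in limma was 0.132 for Wap, 0.243 for Lalba, 0.400 for Csap1 and for Cldn4, and 0.461 for Cdh1.

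The other named genes lower on SPI than on GEN, also without passing, were RT1-CE16 (-2.05), Reg3b (-1.74), Scgb1d2-ps1 (-1.44), Il17b (-1.38), Irf2bpl (-1.29), Plekhb1 (-1.22) and Mapkapk3 (-1.10). Those higher on SPI were Uqcc3 (1.07), Tmub2 (1.02), the integrin-linked kinase Ilk (0.99), Acy3 (0.93), Acvr2a (0.87), Rtn4rl1 (0.82), the adaptor Bcar1 (0.81), the vesicle SNARE Sec22b (0.80), the homeobox gene Meis2 (0.79), Vwf (0.77), the centromere gene Cenpx (0.77) and the metalloproteinase Mmp17 (0.74). Reg3b had 377 ± 63.3 (SD, n = 3) on GEN, where its difference from CAS was -0.08 ± 0.29. A dim other probe set of Irf2bpl stood at -0.28. Ngfr, a neurotrophin receptor of the Schwann cell list (0.67), and the early growth response gene Egr3 of the immediate early list (-0.87) passed adjusted over the list alone, although neither list was called and 0 passed over all genes.

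Camera called 9 lists between SPI and GEN, 1 higher on SPI and 8 lower. Luminal epithelial genes were lower in 16 of 17 members, with a list mean of -0.62 ± 0.24 (SE) and an adjusted p of 6.71e-12 (adjusted p = 0.595 with an estimated correlation, unadjusted 0.0401). Adjusted over the list alone, 10 members were lower on SPI: Cldn4 (-1.15), Ocln (-0.75), Cd9 (-0.79), Epcam (-0.92), Cdh1 (-1.13), the simple epithelial keratins Krt8 (-0.91) and Krt18 (-0.64), Rab25 (-0.75), Cldn3 (-0.74) and Spint2 (-0.58). None of the 10 passed over all genes. Over the alternatives Epcam lay between -1.02 and -0.58. Milk genes were lower in 17 of 18 members (mean -0.66 ± 0.28, adjusted p = 2.87e-08, and 0.595 as the adjusted p with an estimated correlation), and Wap and Lalba passed adjusted over the list alone. Endothelial genes were higher in 13 of 17 members (mean 0.25 ± 0.14, adjusted p = 0.000556, and 0.595 as the adjusted p with an estimated correlation), and Vwf, the von Willebrand factor, passed adjusted over the list alone at 0.77 ± 0.20. SPI 4, with the actin ratio of 7.77, had the lowest luminal and milk means and the highest endothelial mean of its diet. Without it the luminal mean was -0.42 and the milk mean -0.48, and both stayed called.

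Basal and myoepithelial genes were lower on SPI in 10 of 15 members (mean -0.31 ± 0.19 SE, adjusted p = 0.0278, and 0.612 as the adjusted p with an estimated correlation), with Lgals7 at -1.04 and Krt5 at -0.82. Fatty acid oxidation genes were lower in 16 of 22 (mean -0.19 ± 0.09, adjusted p = 0.0147, and 0.595 as the adjusted p with an estimated correlation), with the thiolase Acaa2 at -0.81 and Pdk4, which restrains glucose oxidation, at -1.09. Fatty acid synthesis genes were lower in 13 of 18 (mean -0.19 ± 0.10, adjusted p = 0.0233, and 0.595 as the adjusted p with an estimated correlation), with the fatty acid synthase Fasn at -0.78 and Gpd1 at -0.46. Antioxidant genes were lower in 17 of 26 (mean -0.16 ± 0.14, adjusted p = 0.0178, and 0.612 as the adjusted p with an estimated correlation), with Gsta1 at -0.64. Mast cell genes were lower in 9 of 10 (mean -0.40 ± 0.39, adjusted p = 0.0178, and 0.612 as the adjusted p with an estimated correlation), with Slc18a2 at -0.54. Macrophage genes were lower in 17 of 19 (mean -0.23 ± 0.39, adjusted p = 0.0362, and 0.702 as the adjusted p with an estimated correlation), with Gpnmb at -0.67. In these 6 lists 0 members passed adjusted over the list alone or over all genes. The basal call was lost without GEN 1 (-0.22), GEN 5 (-0.27), SPI 4 (-0.17) or SPI 5 (-0.30), and the oxidation call without GEN 5 (-0.12). Krt5 stood at -0.52 without SPI 4, Fasn at -1.22 without GEN 3 and -0.46 without GEN 5, and Pdk4 at -0.72 with the actin ratio as a covariate. Over all the alternatives Lgals7 lay between -1.34 and -0.46, Krt5 between -1.05 and -0.37 and Gpnmb between -0.84 and -0.38. The synthesis call was lost without GEN 1 (-0.16), GEN 5 (-0.11) or SPI 4 (-0.14), with a mean of -0.30 without GEN 3. The antioxidant call was lost without GEN 3 (-0.06) or SPI 2 (-0.11). The mast cell call was lost without any 1 of GEN 3 (-0.17), GEN 5 (-0.31), SPI 2 (-0.33), SPI 3 (-0.34) or SPI 4 (-0.28), and its mean was -0.71 without GEN 1 and -0.64 without SPI 5. The macrophage call was lost without SPI 2 (-0.24), SPI 3 (-0.13) or SPI 4 (-0.12) and turned to 0.05 without GEN 3, with means of -0.44 without GEN 1 and -0.43 without SPI 5. With the actin ratio as a covariate, chosen after the arrays were seen, the calls of the synthesis (-0.16), antioxidant (-0.13), mast cell (-0.15) and macrophage (-0.07) lists were lost, and with no filter those of the antioxidant (-0.10) and macrophage (-0.17) lists.

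limma called 0 of 9520 probe sets between SPI and GEN, with a smallest adjusted p of 0.132. At an unadjusted p under 0.05 there were 757, of which 352 were higher on SPI and 405 lower, against 476 expected by chance. eBayes without trend and the plain test gave 0 adjusted calls, with 761 and 687 at an unadjusted p under 0.05. With arrays centred on their median the split was 612 higher and 272 lower, a share of 69.2% higher against 46.5%. The groups did not overlap for 809 probe sets (8.50%), where chance gives 5.71%. The unadjusted count was 500 without GEN 3, 490 without GEN 5 and 502 without SPI 4. Single probe sets passed without SPI 2 (RT1-CE16, -2.58, adjusted p = 0.0181 in limma, 0.0181 to 0.998 over the alternatives) and without GEN 5 (Rpl37a, -1.18, noted after its values were seen). With only the 2 groups in the fit, Il17b (-1.38, adjusted p = 0.0325 in limma, 0.0325 to 0.998 over the alternatives) and a probe set with no gene symbol (2.22, noted after its values were seen) passed.

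The receptors of estrogen and progesterone lay below the filter and were not tested. Esr1, the estrogen receptor alpha, had signals of 11.2 ± 1.56 (SD, n = 3) on CAS, 14.2 ± 0.804 (SD, n = 4) on SPI and 14.4 ± 1.66 (SD, n = 3) on GEN. Esr2, the estrogen receptor beta, had 6.90 ± 3.47 (SD, n = 3), 17.1 ± 8.54 (SD, n = 4) and 5.37 ± 2.44 (SD, n = 3). Pgr, the progesterone receptor, had 144 ± 46.5 (SD, n = 3), 110 ± 27.8 (SD, n = 4) and 123 ± 23.9 (SD, n = 3). The list of genes of the estrogen and progesterone response had 11 tested members and was called neither on SPI nor on GEN. Against CAS its mean was -0.16 ± 0.06 (SE) on SPI (adjusted p = 0.408 in camera, 0.590 by fry). On GEN it was -0.17 ± 0.06 (adjusted p = 0.380 in camera, 0.583 by fry). The 95% intervals of these means, not adjusted over lists, excluded 0 (-0.30 to -0.01 on SPI, -0.33 to -0.02 on GEN). Both differences share the CAS arrays.

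Also called in no comparison were the lists of cholesterol synthesis, Wnt signalling, Notch signalling, insulin, IGF and PI3K signalling, apoptosis and p53, skeletal muscle, immediate early and heat shock genes, and the circadian clock. The smallest adjusted p of these 9 lists, with the receptor response, was 0.208, for Wnt signalling. Skeletal muscle genes had a mean of -0.28 ± 0.19 (SE) on SPI and -0.19 ± 0.20 on GEN against CAS. These rested on CAS 1, whose mean was 9.30, where CAS 2 had 8.59, CAS 3 8.47, the SPI arrays a mean of 8.51 and the GEN arrays 8.60. The muscle actin Acta1 had a signal of 710 ± 886 (SD, n = 3) on CAS. The lists of brown adipocytes, erythroid cells and skin keratinocytes had 2, 3 and 4 genes above the filter and were not tested. Over the 3 comparisons camera called 30 of 78 tests, and 0 with an estimated correlation or by fry; the unadjusted p with an estimated correlation was under 0.05 in 3. In either direction, fry called 1, the Schwann cell list for GEN against CAS (adjusted p = 0.00239).

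The responses to SPI and GEN, each against the same CAS arrays, correlated across the 9520 probe sets with a Pearson r of 0.432, and 63.0% of probe sets had the same sign. Simulated unchanged groups of the same sizes, which also shared 1 reference group, gave a mean r of 0.521 (from -0.412 to 0.966 over 100 draws), and 65 of 100 draws had an r as large. The covariance was 0.0297 against a simulated 0.0337, with 49 draws as large. At an unadjusted p under 0.01, 34 probe sets were higher on SPI and 45 on GEN, and 8 on both, where the simulations with a shared reference gave a mean of 12.5 (from 0 to 191) and 27 of 100 draws gave as many. These were Apod, Car2, Fabp3, Mbp, Rfc3, Scn7a, Tfrc and a probe set with no symbol. Lower were 68 on SPI and 50 on GEN, and 10 on both, where the simulations gave a mean of 13.8 (from 0 to 362) and 22 of 100 draws gave as many; among them were P3h3, Pi16, Cdh22, Adgre5, Fbn1, Coro2b, Cotl1 and Akr1c3. The overlap thus lay within what the shared CAS arrays alone can give, and those arrays were too few to split. The simulated ranges were wide, so the simulations cannot exclude a shared response either.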

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

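The tests with the actin ratio, the basal genes, the T and B cell genes and the RT1-Bb probe sets were chosen only after the result was seen. The counts of splits were planned, and each includes the real grouping. In 90 groups of 4 SPI arrays, 4 had an array farther from the other 3 than Dixon's 95% critical value allows, where chance gives about 4.5. SPI 5 was above the other SPI arrays for the mast cell list (gap 0.840 of the range) and for Pi16 (0.843), and below them for Sec22b (0.955). SPI 4 was below the others for Spn (0.848).

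The luminal epithelial genes were lower on SPI than on GEN, by -0.62 in the list mean. Of the 35 splits of these 7 arrays, 2 gave as large a mean in either direction, of which 1 was the real grouping. The other, at 0.66, set the 3 GEN arrays with SPI 2 above the remaining SPI arrays. Chance could thus not be excluded. With the actin ratio as a covariate the difference was -0.51 (95% interval -1.11 to 0.09), so the ratio took up a small part. The interval then held 0, which leaves RNA degradation on some arrays open. Camera kept its call (adjusted p = 2.56e-10), but its preset correlation lay below the 0.579 estimated for this list. The kept call therefore cannot decide on RNA degradation. The SPI minus GEN difference was lower in the luminal than in the basal list by -0.31 (95% interval -0.66 to 0.04), which left open whether the SPI pools held a lower share of epithelium as a whole. An effect of diet on luminal cells stays open and untested by other means.

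The macrophage genes were lower on SPI than on CAS, by -0.66 in the list mean. Of the 35 splits, 7 gave as large a mean in either direction, with 1.04 as the largest other size, so chance could not be excluded. With the actin ratio as a covariate the difference was -0.62 (95% interval -1.58 to 0.34), so the ratio took up little of it. Since the interval held 0 without the covariate too (-1.59 to 0.27), the spread between arrays leaves RNA degradation open. Camera kept its call (adjusted p = 4.82e-07), but its preset correlation lay below the 0.592 estimated for this list. That call therefore cannot decide on RNA degradation either. Lymph node tissue in the CAS pools would bring T and B cell genes, and the mean of the 2 above the filter differed by 0.0504 (95% interval -0.15 to 0.25); the median signal of the 12 such genes was 75.0, so most were too dim to decide. An effect of diet on immune cells stays open and untested by other means.

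RT1-Bb, a class II antigen gene chosen after its values were seen, was lower on SPI than on CAS in its first probe set, where SPI 2 stood at 9.77 and the other SPI arrays at 6.11 to 6.65. The mean of 4 partner genes of class II was also lower, by -0.77 (95% interval -1.51 to -0.04), as fewer class II cells in the SPI pools would give. The SPI minus CAS difference of RT1-Bb was lower than that of these partners by -2.35 (95% interval -4.34 to -0.37), and that of its first probe set lower than that of its second by -3.34 (95% interval -5.89 to -0.79). The probe set was picked because its difference was the lowest of all, so neither comparison decides between fewer class II cells, MHC haplotypes that differ between outbred animals and an effect of diet on this gene.

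For SPI against CAS, 18 of 35 splits gave as many probe sets at an unadjusted p under 0.05 (459, highest other 1052) and 3 of 35 as many called lists (10, highest other 10), so chance could not be excluded for either. For SPI against GEN, 6 of 35 splits gave as many probe sets (757, highest other 1514) and 6 of 35 as many lists (9, highest other 12), so chance could not be excluded either. For GEN against CAS, 3 of 10 splits gave as many probe sets (561, highest other 816) and 1 of 10 as many lists (11, highest other 10). These 10 splits are too few for a share under 0.05. Probe sets with an adjusted p under 0.05 in limma arose in 2 of the 34 other splits for SPI against CAS, at most 2. The same held for 1 of 9 for GEN against CAS and 3 of 34 for SPI against GEN, with at most 1 in each.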

How the results depend on the processing

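The actin ratio as a covariate and the fit without SPI replicate 4 for GEN against CAS were tests chosen only after the arrays were seen. The count of probe sets with an adjusted p under 0.05 was 0 in each comparison and stayed 0 under the other choices, except as follows. For SPI against CAS it was 0 to 2 on leaving out 1 array. For GEN against CAS it was 2 with the lowest 60% left out and 1 with 1 probe set per gene, where fewer probe sets were tested, and 0 to 1 on leaving out 1 array. For SPI against GEN it was 2 with only the 2 groups compared in the fit and 0 to 1 on leaving out 1 array. The 30 list calls became 0 with an estimated correlation and 0 by fry. Of 180 named gene results, 179 kept their direction in each setting where they were tested. These genes were picked from the same arrays for a small p, many of them also for groups without overlap. Their kept direction was therefore largely fixed in advance and lends the differences no weight. Pmp22 between SPI and CAS was 0.15 and lay between -0.0131 and 0.26 on leaving out 1 array. The macrophage list between SPI and GEN lay between -0.44 and 0.0487. The correlation of the SPI and GEN responses lay between 0.311 and 0.608. Apart from the reasons given, the cause was not tested.

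The count at an unadjusted p under 0.05 moved from 459 for SPI against CAS to 776 with no filter, 298 with the lowest 60% left out, 726 without CAS replicate 2 and 298 without SPI replicate 3. It moved from 561 for GEN against CAS to 884 with no filter and 353 without GEN replicate 5. It moved from 757 for SPI against GEN to 1213 with no filter, 498 with the lowest 60% left out, 500 without GEN replicate 3, 490 without GEN replicate 5 and 502 without SPI replicate 4. With no filter 15866 probe sets were tested, and 6347 with the lowest 60% left out, against 9520. The counts under these filters mainly followed the number tested. With the replicate block the adjusted counts were 0, 0 and 0, the unadjusted counts 270, 416 and 286 and the list calls 25; 10 of the 30 list calls were not among these, such as the luminal list between SPI and CAS (-0.0280). The 6 pairs of arrays with the same number had correlations of their deviations from -0.183 to 0.155, with 1 over 0.1. The 27 other pairs had -0.396 to 0.302, so no pairing by number was seen. So few pairs cannot exclude one. No array carried a measure of background in the table used here, so the limit set by dim signal was only the filter at a signal of 162.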

Other observations

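The genes and arrays in this part were chosen after their values were seen, and no tests beyond those given above were run on them. Muscle genes stood out on single arrays. Acta1, the skeletal muscle actin, had signals of 710 ± 886 (SD, n = 3) on CAS, 109 ± 70.6 (SD, n = 4) on SPI and 237 ± 75.6 (SD, n = 3) on GEN, and the creatine kinase Ckm had 602 ± 659 (SD, n = 3), 228 ± 59.3 (SD, n = 4) and 281 ± 84.1 (SD, n = 3). CAS 1 had the highest mean of the skeletal muscle list, 9.30, where the other 9 arrays had 8.43 to 8.65. CAS 3 stood apart on the second principal component, with a score of 31.5, and had the highest mean of the macrophage list, 10.16, where CAS 2 had 8.96.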
